A study of Drosophila melanogaster with 4 samples.

How the data were processed

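The series profiled HP1c, one of the Drosophila melanogaster HP1 family of chromodomain proteins, by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Oregon-R animals of the third larval instar. The labels name 4 samples, 2 HP1c ChIP libraries and 2 input DNA libraries, numbered replicate 1 and 2 in each group. Per the labels' protocols, larval tissue was homogenised and fixed with formaldehyde, the nuclei were lysed with SDS and sonicated, and the chromatin was precleared on protein A beads before overnight immunoprecipitation. The antibody was an affinity-purified rabbit polyclonal serum raised against a bacterially produced HP1c fragment.

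The authors deposited lists of enriched regions, each with a position and 1 score, and no read counts or signal tracks were used here. One list belongs to each ChIP library and was therefore called per library. Another list, called the combined list below, covers the replicate set, and how the replicates were joined for it is not given in the sources used here. No list of the input libraries was analysed here, so their role as background can be described only through the authors' region calls. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.7. The file headers name FlyBase release 5 as the genome build. The region caller, its threshold, the treatment of reads that align to several places and the scale of the score are not given in the sources used here. The score per region is the authors' own value, as deposited, and it served to rank, filter and match regions, to compare groups of regions by their median within a list and to set its sign beside the name of each row of the combined list. Sequencing depth is unknown for all libraries, so no limit based on read numbers is given. Intervals printed for shares of regions are exact Clopper-Pearson 95% binomial intervals over regions. They cover counting error only.

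The combined list held 6902 rows, of which 11 were named as depleted and were kept out of the comparisons. In it, 1 region started at position 0 and its start was set to 1. Regions did not overlap each other within any list. Sequence lengths came from the file headers, which name 14 sequences with 169 Mb in all: the arms 2L, 2R, 3L, 3R and X, chromosome 4, 6 scaffolds of assembled heterochromatin (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet), and the unplaced collections U and Uextra. The gene table at hand was of release 6 and coordinates were not carried between releases. Start sites and the gene lists fixed beforehand were therefore not tested, and regions are named by position in release 5 instead of by gene. The positional rule set beforehand named the 10 highest-scoring combined regions that overlapped a region of both replicates.

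Overlap between lists required at least 1 shared bp. The overlap of the replicate lists was compared with 1000 circular shifts of one list within each sequence (one-sided; the smallest p the shifts can give is 0.001). The shifts do not model gaps or repeats that cannot be aligned to. Coverage was the percent of a sequence's length inside regions, computed per replicate and given as mean ± SD (n = 2). X was compared with the 4 autosomal arms over 1 Mb windows by a two-sided permutation test of the mean with 100000 permutations (smallest p 1e-05). Neighbouring windows are not independent. Heterochromatin scaffolds were compared with the 5 main arms and chromosome 4 by an exact two-sided permutation test over the 924 splits of these 12 sequences. Nothing in the labels says whether the replicates came from separate larval collections, so the SD may be technical.

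On simulated lists of 1075 regions per list on the main arms, the overlap step found 60.5% of regions shared where 60% had been planted, and called all 20 such pairs. The planted regions were exact copies, and the others were placed apart from the first list. The share found was thus set by construction and checks the counting only. The overlap step called 1 of 20 pairs of lists placed at random. In those pairs 4.72% of regions overlapped, against 23.4% on average in the shifts of the longer real lists for replicate 1. The window test called 46 of 50 simulations with a planted X ratio of 1.3 and 4 of 50 with a ratio of 1. Both steps ran on the simulations with fewer shifts or permutations than on the real data. All simulated windows were drawn independently from the autosomal windows of replicate 1. Dependence between neighbouring windows was therefore not simulated, and the rate of false calls on real arms is not known from it. Alternatives, fixed before the data were examined, were a reciprocal overlap of 50%, the upper 50% of each list by score and merging of regions less than 500 bp apart. Also fixed then were the main arms and chromosome 4 without the other sequences, either replicate alone and the combined list in place of the replicates. Windows of 0.5 and 2 Mb were added after seeing the data. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.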

Results

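Genomic regions enriched for HP1c were mapped by ChIP-seq in whole wild-type larvae of the third instar, in 2 ChIP replicates with 2 matching input libraries. HP1 proteins are non-histone chromosomal proteins, and HP1c is the family member known mainly from euchromatin, whereas HP1a is the main component of pericentric heterochromatin. The design asks where HP1c lay along the chromosomes at this stage and whether the replicates gave the same places. The authors' list for replicate 1 held 5586 regions over 14.5 Mb and that for replicate 2 held 5946 regions over 16.1 Mb. The combined list held 6891 enriched regions over 18.1 Mb. The number of reads behind the lists is unknown.

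HP1c-enriched regions lay mainly on the 5 main arms, which carried 5387 of the regions of replicate 1 and 5774 of those of replicate 2. The autosomal arms were covered to similar extents. Coverage was 11.2% ± 0.9 (SD, n = 2) on 2L, 12.7% ± 1.1 on 2R, 11.8% ± 0.65 on 3L and 11.3% ± 0.91 on 3R. The X chromosome was covered more densely, at 15.2% ± 1.2, with 55.4 ± 2.6 regions per Mb against 44.9 ± 2.2 over the autosomal arms together. Over 1 Mb windows, X exceeded the autosomal arms 1.32-fold, with a bootstrap 95% interval over windows of 1.17 to 1.49 (22 X windows against 97 autosomal windows; permutation test, p = 2e-05). The ratio was 1.32 in each replicate taken alone. The levels depend on the authors' threshold: in the upper 50% of each list by score, 6.66% to 7.45% of each autosomal arm and 9.63% of X were covered. Taken as whole arms, 1 X against 4 autosomal arms allows no p below 0.2, although X lay above every autosomal arm in both replicates.

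**Figure D1:**
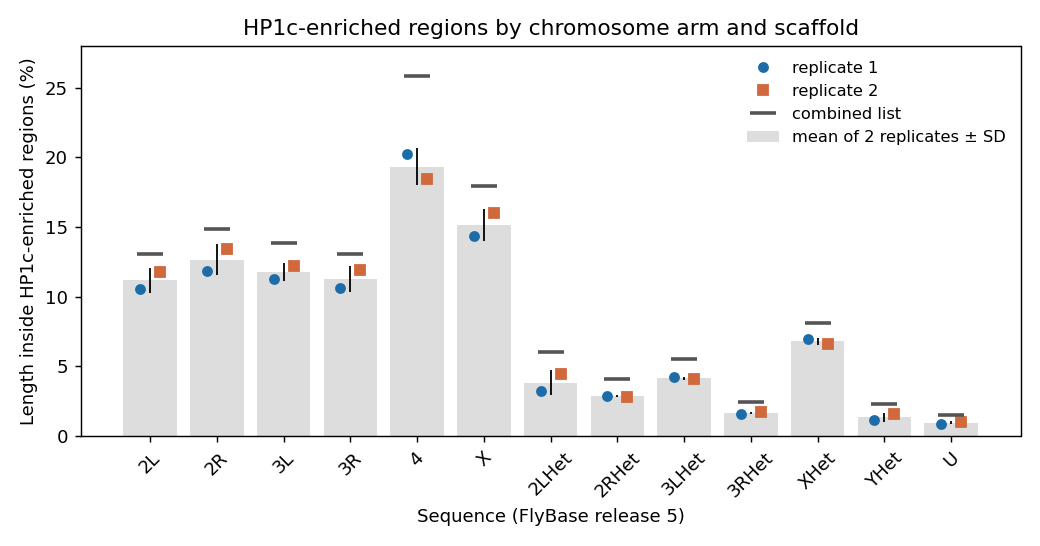
Percent of the length of each sequence inside HP1c-enriched regions (vertical axis) for the main arms, chromosome 4, the heterochromatin scaffolds and the unplaced collection U (horizontal axis). Grey bars are the mean of 2 replicates with SD, points are the replicates and dashes the combined list. Chromosome 4 stands highest at 19.3%, X follows at 15.2%, and all heterochromatin scaffolds lie below 2L at 11.2%.

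Chromosome 4, the small dot chromosome whose genes lie in a largely heterochromatic setting, had the highest coverage. Regions took 19.3% ± 1.3 (SD, n = 2) of its 1.35 Mb, which was 1.67 ± 0.24 times the coverage of the autosomal arms. The number of regions per Mb, 53.3 ± 9.4, was not above the 55.4 ± 2.6 of X. Against the autosomal arms it was 59.9 to 43.3 in replicate 1 but 46.6 to 46.5 in replicate 2. In replicate 2 the median width on chromosome 4 was 3508 bp, against 2304 bp in the whole list. Windows of the length of chromosome 4 were placed every 50 kb along the main arms. Of these 2248 windows, 76 reached the mean coverage of chromosome 4, and all 76 lay on X. Neighbouring windows share most of their sequence, so these counts are not counts of separate places. With replicate 1 alone 21 windows did so, all on X, and with replicate 2 alone 168, of which 142 lay on X. In the upper 50% of each list by score, 13.2% of chromosome 4 was covered. The widest region of the combined list that overlapped both replicates also lay on this chromosome, at positions 71810 to 91186, and measured 19377 bp. The replicates differed here. Replicate 1 listed 81 regions on chromosome 4 and replicate 2 listed 63, the reverse of their order on each main arm, and coverage was 20.3% and 18.4%. With 1 such chromosome, its excess over the arms was not tested.

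The scaffolds named as heterochromatin carried few HP1c regions for their length. This holds for these scaffolds alone, and chromosome 4 was counted apart. The 6 scaffolds, 9.28 Mb in all, held 83 regions in replicate 1 and 72 in replicate 2, or 1.49% (95% interval 1.19 to 1.84) and 1.21% (0.949 to 1.52) of the lists, while they make up 5.50% of the sequence. Their pooled coverage was 2.96% ± 0.0075 (SD, n = 2), 4.17-fold below the 12.3% ± 0.93 of the main arms. All 6 scaffolds were covered less than all 5 main arms and chromosome 4 (exact permutation test, two-sided p = 0.00216, the smallest that these 12 sequences allow). XHet, the shortest scaffold, was covered most, at 6.79% ± 0.23. The values were 4.15% ± 0.12 on 3LHet, 3.84% ± 0.87 on 2LHet, 2.87% ± 0.054 on 2RHet and 1.65% ± 0.067 on 3RHet. YHet was lowest at 1.35% ± 0.32, with 2 regions in replicate 1 and 3 in replicate 2. The unplaced collection U was covered to 0.958% ± 0.11, and no region was listed on Uextra. How reads from repeats were aligned is not given in the sources used here. Coverage was taken over full sequence lengths, with gaps and sequence that cannot be aligned to left in. How far these account for the low values on the scaffolds, U and Uextra was not tested.

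Within the main arms coverage ranged from 3.34% to 21.9% between windows of 1 Mb, the shorter last parts of arms included. The densest window was X at 13 to 14 Mb with 21.9% ± 0.26 (SD, n = 2), followed by X at 11 to 12 Mb with 21.8% ± 1.1 and X at 6 to 7 Mb with 21.2% ± 1.5. X held 8 of the 10 densest windows and 22 of all 119. The densest autosomal window was 3L at 16 to 17 Mb with 20.2% ± 0.30. The sparsest was the shorter last window at the centromeric end of 3L, from 24 to 24.5 Mb, with 3.34% ± 0.036. Among full windows the sparsest was 2L at 17 to 18 Mb, with 4.08% ± 0.93. The profile was shared by the replicates (Pearson r = 0.98 and Spearman rho = 0.97 across 119 windows, which are not independent replicates), with replicate 2 higher in 115 of the 119 windows.

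**Figure D2:**
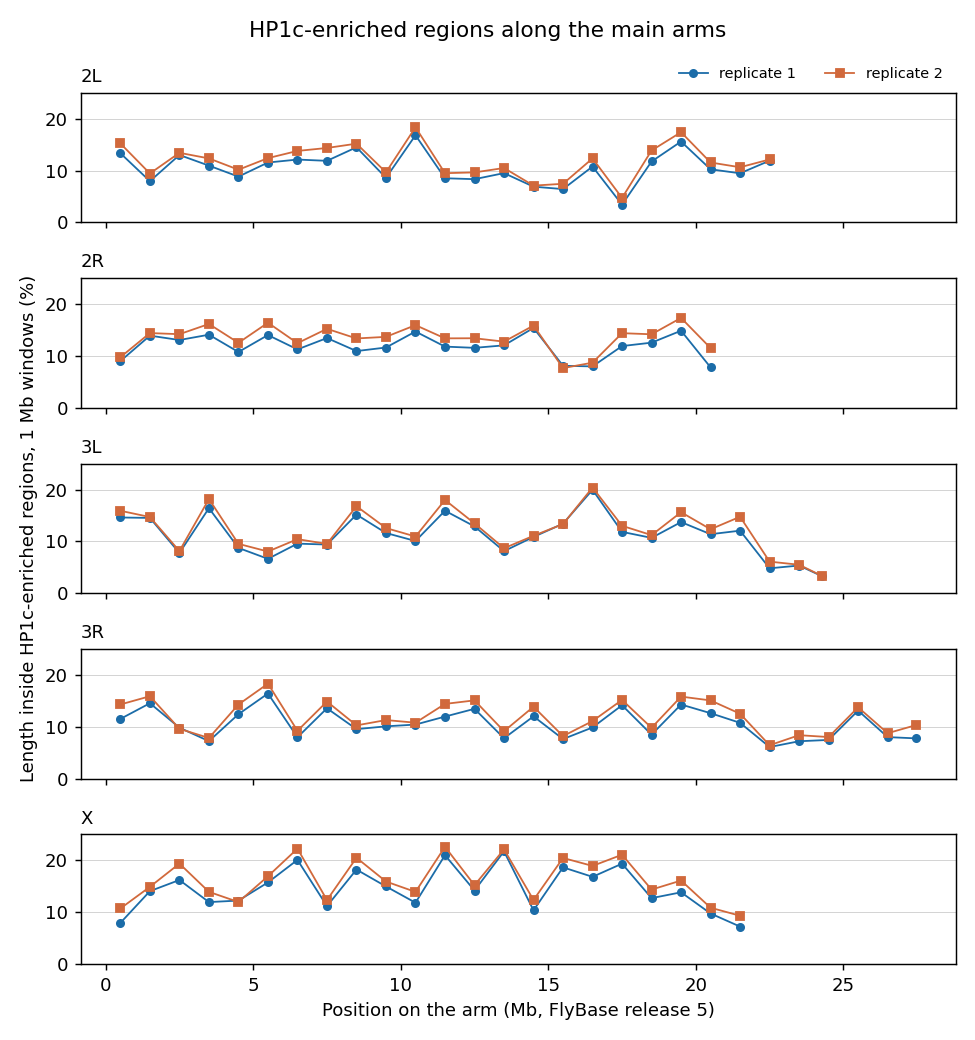
Percent of each 1 Mb window inside HP1c-enriched regions (vertical axis) against position on the arm in Mb (horizontal axis) for the 5 main arms. Blue circles are replicate 1 and orange squares replicate 2. The replicates follow each other along every arm, and X peaks at 21.9% at 13 to 14 Mb. The shorter last window of 3L, at its centromeric end, falls to 3.34%.

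The strongest regions lay on the main arms, as did 4770 of the 4901 combined regions that overlapped both replicates. These arms carried 6595 of all 6891 combined regions, so this lies close to their share of the list. Scores were not lower on the heterochromatin scaffolds. Their median score in the combined list was 0.86, against 0.79 over all its regions. The values were 1.05 against 0.95 in replicate 1 and 1.65 against 1.14 in replicate 2. The strongest regions were wider than the typical region, and width rose with score across the combined list (Spearman rho 0.76). The 10 highest-scoring combined regions that overlapped both replicates measured 2509 to 3949 bp, against a median of 2251 bp in the combined list, with the authors' scores between 4.03 and 4.33. Of these, 4 lay on 2R, 2 on 3R, 2 on 2L, 1 on X and 1 on 3L. The highest, X 5222148 to 5225218, scored 4.33. It was followed by 3R 11054014 to 11056654 with 4.15, 2R 8766172 to 8768946 with 4.14, 2R 11014234 to 11018132 with 4.13 and 2R 4996040 to 4999542 with 4.12. The others were 2R 2548438 to 2552386 with 4.09, 2L 18687658 to 18690768 with 4.06, 2L 7798694 to 7801508 with 4.05, 3R 9484992 to 9488136 with 4.03 and 3L 21720594 to 21723102 with 4.03. All 10 ranked among the first 36 regions of replicate 1 and the first 14 of replicate 2. Which genes lie at these positions was not analysed here.

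Regions were short compared with the arms they lay on, and most spanned a few kilobases. The median width was 2262 bp in replicate 1 (quartiles 1974 and 2783) and 2304 bp in replicate 2 (2010 and 2920), with a minimum of 1301 bp in both. Regions wider than 5000 bp made up 4.56% of replicate 1 and 5.68% of replicate 2. Wider regions scored higher, with a Spearman rho of 0.78 in replicate 1 and 0.77 in replicate 2, across regions, which are not independent replicates. In the upper 50% of each list by score the mean rho was 0.29.

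The replicates placed HP1c at largely the same positions. A region of replicate 2 overlapped 5047 of the 5586 regions of replicate 1 (90.4%), and a region of replicate 1 overlapped 4976 of the 5946 of replicate 2 (83.7%). Circular shifts gave 23.4% and 21.9% on average and 37.7% and 35.1% at most (1000 shifts, one-sided permutation p = 0.001 for each, the smallest they can give). The lists shared 13.1 Mb, a base-pair Jaccard index of 0.75 against 0.066 in the shifts. They had 1 region in common with identical ends, so the lists are not copies of each other. Overlap depended on score. In the highest decile of replicate 1, 99.8% of regions were overlapped (95% interval 99.0 to 99.995), against 73.9% (70.0 to 77.5) in the lowest. For replicate 2 the shares were 99.8% (99.1 to 99.996) and 47.4% (43.3 to 51.5). Regions found in 1 replicate alone had median scores of 0.47 in replicate 1 and 0.40 in replicate 2, against 1.07 and 1.39 for overlapped regions of the same lists. They were also narrower, with median widths of 1694 and 1881 bp against 2322 and 2420.5 bp. A wide region meets an overlap of 1 bp more easily, and score and width were not separated here.

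**Figure D3:**
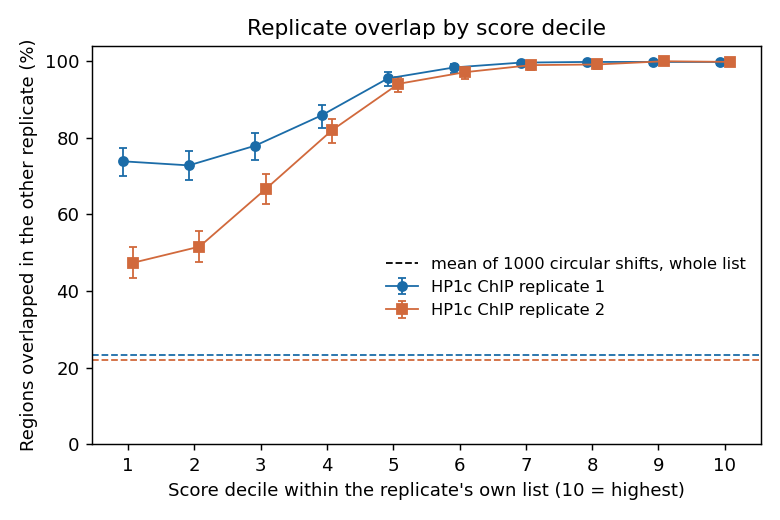
Percent of regions overlapped by at least 1 bp in the other replicate (vertical axis) by score decile within the replicate's own list (horizontal axis, decile 10 highest), with exact 95% binomial intervals. Blue circles are replicate 1, orange squares replicate 2, and dashed lines the mean of 1000 circular shifts of the whole list. Overlap rises from 73.9% and 47.4% in the lowest decile to 99.8% in the highest in both replicates.

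Most regions of the combined list overlapped a region of both replicates. Of its 6891 enriched regions, 4901 (71.1%, 95% interval 70.0 to 72.2) overlapped both, 911 (13.2%) overlapped replicate 2 alone, 437 (6.34%) replicate 1 alone and 642 (9.32%) neither. Regions in both had a median score of 1.22 and a median width of 2513 bp. Those in neither had a median score of 0.33 and a median width of 1232 bp. On the main arms 72.3% (71.2 to 73.4) of combined regions overlapped both replicates, against 47.1% (37.2 to 57.2) on chromosome 4 and 48.8% (39.7 to 58.0) on the heterochromatin scaffolds. The list covered 98.2% of the regions of replicate 1 and 98.9% of those of replicate 2. In the combined list 100% of regions ended on an even position, against 49.2% in replicate 1 and 49.6% in replicate 2. Its regions were thus not copied from the replicate lists. The combined list was made from the same libraries and is not an independent sample.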

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

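The tests in this part were chosen after the results they bear on had been seen, except that of X coverage in the upper 50% of each list by score.

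The combined list holds 11 rows named as depleted, which were flagged because no comparison used them. They are 1667 to 1813 bp wide, lie on 2L, 2R, 3L and 3R, and have scores from -0.098 to -0.00069. Of the 11, 8 overlap an enriched region of a replicate, 7 in replicate 2 and 1 in replicate 1, against 2.24 on average and 7 at most in 1000 circular shifts (one-sided permutation p = 0.001). All rows named as enriched have scores above 0 and all rows named as depleted have scores below 0. The name thus matched the sign of the combined score in every row. The overlap is no independent support for this, because the combined list was made from the same libraries. The overlapped regions were weak, with scores of 0.025 to 0.30 in replicate 2, all within its lowest decile, and 0.39 in replicate 1, and no row overlapped a region of both replicates, so gain or loss of HP1c at these places stays open, and no biological explanation was tested.

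The higher coverage of X is a pattern to follow up. An excess made by weak regions near the calling threshold is argued against by the upper 50% of each list, where the ratio of X to autosomal coverage was 1.42 (permutation p = 1e-05). Wider regions alone are argued against as well, since X had 1.23 times as many regions per Mb, while the mean width was 1.05 times that on the autosomal arms. The copy number of X and gene density on X were not tested and stay open, as the sex of the larvae is not given and no annotation of the build was at hand.

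Chromosome 4 regions of replicate 1 were often missing from replicate 2. Of 81 regions, 28 (34.6%) had no overlap, against 8.98% on the main arms. Low scores are argued against as the whole cause, because main arm regions matched on score decile gave 10.6% (one-sided permutation p = 1e-05). A difference of replicate 1 over all heterochromatin may contribute, since its heterochromatin scaffold regions were missing in 18.1% of cases against 6.11% for matched regions (permutation p = 4e-05); chromosome 4 lay above the scaffolds in the raw counts (28 of 81 against 15 of 83, Fisher's exact test, two-sided p = 0.0208), but within score deciles 25.8 of its regions were expected to be missing (two-sided permutation p = 0.44), which leaves a difference between them open. In replicate 2 the share on chromosome 4 was 12.7% against 14.5% matched (permutation p = 0.76), and what set replicate 1 apart stays open, with no biological explanation tested.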

How the results depend on the processing

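The 5 results with a test kept their direction and their side of the threshold in all 21 alternatives run. The shares of both replicates and the Jaccard index count among the 5 but measure the same overlap, so they are not separate comparisons. Replicate overlap ranged from 86.6% to 91.4% for replicate 1 and from 81.4% to 85.4% for replicate 2, the ratio of X to autosomal coverage from 1.29 to 1.42 (highest permutation p = 7e-05) and the deficit of heterochromatin scaffolds from 3.34-fold to 4.38-fold. In the upper 50% of each list by score, the share of combined regions overlapping both replicates moved from 71.1% to 73.0%, chromosome 4 over autosomal arms from 1.67 to 1.92, the share of regions on heterochromatin scaffolds from 1.35% to 1.56%, the median width from 2283 to 2653 bp and the rho of width with score from 0.78 to 0.29. The narrower range of scores is part of that setting's construction for width and rho, and the cause was not tested for the others. The combined list put 1.78% of its regions on heterochromatin scaffolds, and the cause was not tested. Coverage of each of the 5 main arms and chromosome 4 fell in the upper 50%, to between 6.66% on 3R and 13.2% on chromosome 4, which removing regions must give, and was higher in the combined list, up to 25.8% on chromosome 4. The share of regions on YHet, 0.043%, was 0.086% in the upper 50%, where all its 2 and 3 regions stayed while the lists were cut, and 0.058% (4 regions) in the combined list. Leaving out either replicate gave 1.50 to 1.83 for chromosome 4 over autosomal arms. The Jaccard index was not run with a reciprocal overlap, which does not apply to bases, and the planned tests of start sites and gene lists were not run. No paired analysis was possible because only the ChIP libraries have lists and the input libraries, which share their replicate numbers, were not analysed here. Read depth is unknown, so whether regions missing from 1 replicate reflect depth cannot be said.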

Other observations

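The tests of the arm ends and of regions in neither replicate were chosen after the values they bear on had been seen. That of the spacing of regions was written before its value was computed, but after coverage over 1 Mb windows had been seen.

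HP1c regions were unevenly spread within the arms. Over 1189 windows of 100 kb, the number of combined regions per window averaged 5.54, with a variance 2.34 times the mean, against 0.89 at most in 1000 random placements of the same regions (one-sided permutation p = 0.001). There were 96 windows with no region and 81 with 12 or more, up to 18. Long stretches between regions, with no region in any of the 3 lists, lay on every main arm. Of these, 48 exceeded 150 kb, 19 of them on 3R, 9 on 2L, 8 on 3L, 6 on 2R and 6 on X. Stretches before the first or after the last region of an arm were not counted. The counts were not adjusted for arm length, and 3R is the longest arm at 27.9 Mb. The longest counted stretch ran over 404 kb of 3L from 13507615 to 13911765. It was followed by 334 kb of X from 21506579 to 21840783 and 327 kb of 2L from 15924083 to 16250707. Gaps in the assembly or in alignable sequence were not marked.

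The ends of the arms next to the centromere did not share one level. The hypothesis that coverage falls next to the centromere on every arm held for 3 of the 5 arms and failed for the others. The centromere-proximal 1 Mb was covered to 4.02% ± 0.14 (SD, n = 2) on 3L and 5.63% ± 1.3 on X, against median windows of 11.9% and 14.9%, and 2R had 9.40% ± 0.53 against 12.8%. On 2L the value was 12.2% ± 0.43 against 11.5%, and on 3R 12.9% ± 2.0 against 10.7%, above the median window in both replicates. Low coverage was not particular to that side: the telomere-proximal 1 Mb was covered to 7.72% ± 2.3 on 2R, 9.35% ± 2.0 on X and 8.20% ± 1.6 on 3R, each below the arm's median window, and to 14.3% ± 1.3 on 2L and 15.3% ± 0.92 on 3L, above it.

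Of the 642 combined regions in neither replicate, 377 were narrower than the narrowest region of the replicate lists, 1301 bp. Regions in neither replicate made up 35.0% of the combined regions on heterochromatin scaffolds (43 regions) and 8.32% of those on the main arms (549 regions) (Fisher's exact test, two-sided p = 3.5e-16). The scores of the 642 reached 3.35, and 55 scored above 1.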
